A study of Mus musculus with 6 samples.

How the data were processed

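Gene expression was measured by RNA-seq in mouse embryonic stem (ES) cells and in differentiated cells derived from them, which the labels call FLICs. Per the labels' protocols, cells of a C57BL/6 background were kept in culture for 96 h and were either left untreated or given OHT, the tamoxifen metabolite hydroxytamoxifen, for 3 days. The labels give the untreated cells as wild-type and the OHT-treated cells as lacking TRF2, the telomere-binding protein encoded by Terf2. No group received OHT without loss of TRF2, so effects of OHT itself cannot be told apart from effects of that loss. RNA was isolated with the RNeasy Mini Kit, and libraries were made with the TruSeq Stranded Total RNA LT kit, per the labels' protocols.

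The authors deposited 1 table of whole-number read counts per gene, with 22600 Ensembl genes and 6 columns, each of which bears the title of 1 library. The deposited counts were not normalized, and the table also has the length of each gene. The submitters' processing notes name Salmon, DESeq2 and the genome build GRCm38, without versions or roles. The aligner settings and the annotation version are not given in the sources used here. Of the deposited lengths, 77.6% were multiples of 3, as in coding lengths without untranslated regions. The 13 mitochondrial genes of the table had a count of 0 in each library, so the mitochondrial list fixed in advance was not tested. Nor is it stated how reads shared by near-identical gene copies were assigned, so counts of single members of such families are uncertain. Symbols were matched for 22509 genes and not for 91. Positions are from GENCODE M21 on GRCm38.

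Total counts ran from 23534551 to 43965309 per library. A count of 0 allows up to 3 counts, which equals 0.0686 to 0.118 CPM per library. Such floors cover counting error only, since the labels name no molecular identifiers.

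The 6 libraries fall into 4 groups by title and treatment label: untreated ES cells (n = 2), ES cells with OHT (n = 2), untreated FLICs (n = 1) and FLICs with OHT (n = 1). Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. The untreated ES cell libraries differed by more than sampling noise (chi-square per degree of freedom 13.9) and were counted as 2 samples.

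Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered by group with filterByExpr, which left 15535, and scaled by TMM. CPM values here are computed from the deposited counts with TMM-scaled library sizes. A quasi-likelihood model with 1 mean per group was fitted over the 6 libraries, and p-values were adjusted by the Benjamini-Hochberg method, with calls at 0.05. The fit had 2 residual degrees of freedom, both from the ES cell pairs, a common biological coefficient of variation of 18.5% and 3.79 prior degrees of freedom. Contrasts that include a single FLICs library assume that it varies like the ES cell libraries. OHT in FLICs was described without a test: a gene was counted when log2(CPM + 1) differed by at least 2-fold and its mean was at least 1 CPM.

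Gene lists were fixed before the data were examined and were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2. They were tested again with an estimated correlation and with fry. With an estimated correlation the camera test rests on the 2 residual degrees of freedom. A call lost there therefore does not by itself count against a list. The estimated correlation ran from -0.0565 for striated muscle to 0.783 for p53 targets, with 0.390 for smooth muscle and 0.352 for mitosis. Where it lies far above the preset 0.01, the p-values of camera at the preset correlation may be too small. In FLICs, the median of each list was placed among 10000 random lists matched on mean expression. The two-cell list overlaps genes that the study is known to name from its own ES cells, so it is not independent evidence. Named genes followed a rule also fixed in advance: Terf2, up to 10 genes per direction with the largest changes, called, with non-overlapping ES cell groups and at least 1 CPM (10 CPM between cell types, 5 CPM for OHT in FLICs), without model names and pseudogenes, and up to 4 members of each list. Where fewer than 5 passed, the 5 smallest p-values were taken as well.

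The procedure was tested on 5 sets of simulated counts for the OHT contrast in ES cells over 15535 genes, each with 200 changed genes. These were drawn from genes with a mean of at least 1 CPM in ES cells, at the spread fitted per gene. The procedure recovered 54.4% of 2-fold, 93.6% of 4-fold, 99.6% of 8-fold and 100% of 16-fold changes. Of its calls, 10.3% were false, above the nominal 5%. In the deposited data the smallest change called was 1.24 on the log2 scale (Icam1), so the recovered shares need not hold there. The alternatives tried were relative log expression scaling, DESeq2 1.42.0, no count filter, a filter of 5 CPM in 2 libraries, a 2-fold minimum, the replicate number as a block, the ES cell libraries alone, each ES cell library left out, and other size rules and pseudocounts in FLICs. Plots were made with matplotlib 3.10.9.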

Results

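The transcriptomes of mouse ES cells and of FLICs, differentiated cells derived from ES cells, were compared with and without OHT, which in this design removes the telomere-binding protein TRF2. The title and design text of the series set the question of how pluripotent and differentiated cells respond to that loss. Total counts were 32277590 and 38670508 in the untreated ES cell libraries, 31518151 and 23534551 in the OHT-treated ES cell libraries, 32302428 in untreated FLICs and 43965309 in FLICs with OHT. The first principal component held 89.7% of the variance and separated FLICs from ES cells. The second held 5.40% and separated OHT-treated from untreated ES cells, and the third held 3.01% and separated the OHT-treated ES cell libraries from each other. By the size rule (at least 2-fold on log2(CPM + 1) and a mean of at least 1 CPM), 0 of 12149 genes differed between the untreated ES cell libraries, and 470 of 12698 between the OHT-treated ones, of which 421 were higher in replicate 2.

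Terf2 (ENSMUSG00000031921, chromosome 8, 107069400 to 107096547, GRCm38), the gene of TRF2, followed the labels in each library. Its count was 554 and 732 in untreated ES cells and 9 and 10 with OHT. The mean fell from 18.9 ± 0.810 CPM (SD, n = 2) to 0.336 ± 0.0787 CPM (SD, n = 2), a log2 fold change of -5.82 (SE 0.26, edgeR adjusted p = 0.00622). In FLICs the count was 268 without OHT and 5 with it, or 8.27 and 0.114 CPM. Of the 7 shelterin genes, which encode the telomere-capping complex, Terf2 was the only one called in ES cells. The median change of that list was -0.12 (camera adjusted p = 0.0745). It passed without untreated replicate 2 (-0.17, adjusted p = 0.0304) and without OHT replicate 1 (-0.27, adjusted p = 0.0448), but was -0.00479 without OHT replicate 2.

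**Figure D1:**
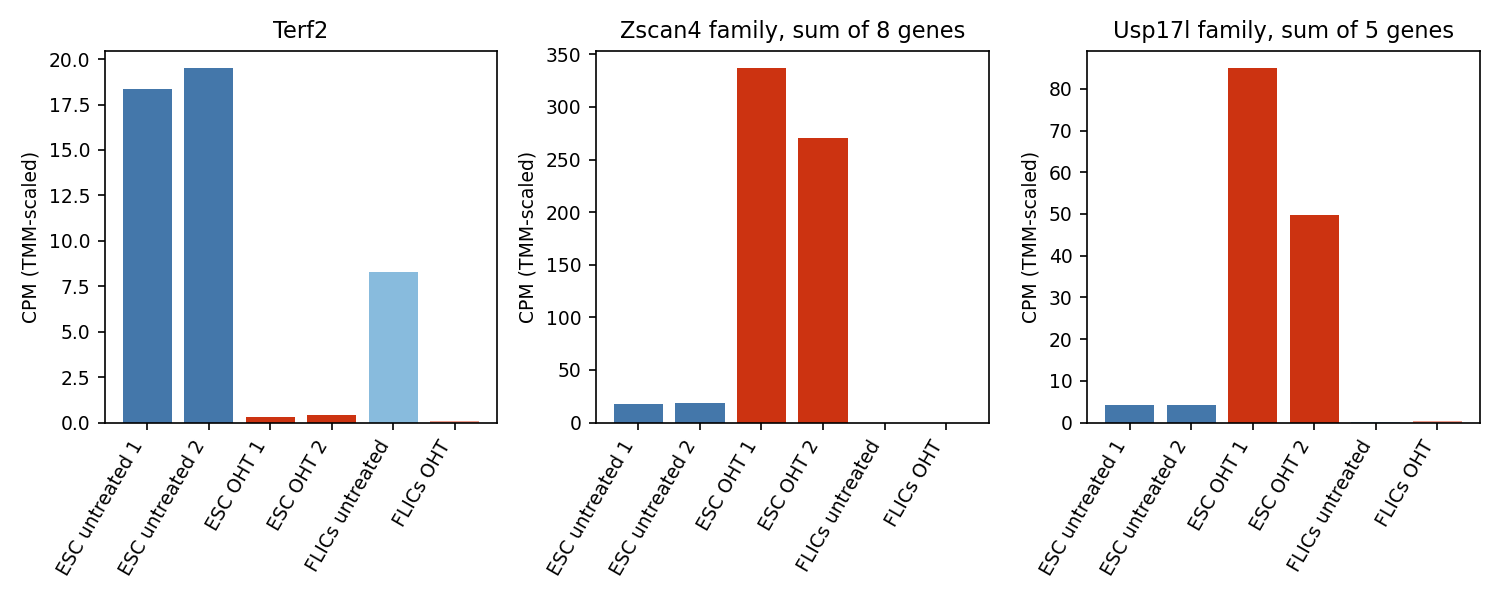
Bars give CPM (TMM-scaled) in each of the 6 libraries for Terf2, for the sum of the 8 Zscan4 genes and for the sum of the 5 Usp17l genes, on linear axes from 0. Terf2 stood at 0.281 and 0.392 CPM in the OHT-treated ES cell libraries, in which the Zscan4 sum stood at 337 and 270 CPM.

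Genes known from the two-cell embryo and from the rare ES cells that resemble it rose in ES cells with OHT. The Zscan4 family, whose members mark that state, went from a summed 17.7 ± 0.679 CPM (SD, n = 2) to 303 ± 46.7 CPM (SD, n = 2), a 17.1-fold difference, and 8 of its 8 genes were called higher. Zscan4d (ENSMUSG00000090714, chromosome 7, 11161374 to 11166159) went from 1.85 ± 0.0543 to 42.0 ± 4.45 CPM, with a log2 fold change of 4.50 (SE 0.20, edgeR adjusted p = 0.00622). Zscan4b, Zscan4c and Zscan4e rose by 4.19, 4.08 and 4.16 on the log2 scale. The Usp17l family of deubiquitinases rose 16-fold in sum, from 4.20 to 67.3 CPM, with 5 of 5 genes called. The other family sums were 26.5-fold higher for Tcstv (1 of 2 members tested called), 4.87-fold for Tdpoz (2 of 4), 3.67-fold for Dux (0 of 4), 3.56-fold for Eif1a-like (3 of 8) and 1.36-fold for Pramef (1 of 9). Members of some of these families, such as Zscan4, are near-identical, so there the sums are firmer than the values of single members. The Zscan4 genes include the pseudogenes Zscan4-ps1, Zscan4-ps2 and Zscan4-ps3. The Dux sum joins Duxf3 with the separate Duxbl genes. The Pramef sum holds all genes whose symbols begin with Prame, Pramel6 and Pramel7 among them. Of the 50 two-cell genes tested, 22 were called higher and none lower, and 43 were called higher when adjusted over the list alone. The list overlaps genes that the study is known to name from its own ES cells, so that count is not independent evidence. The list's median log2 fold change was 3.67, or 3.65 with the members at 0 in one group set at their bound (3 counts over the group). Its camera adjusted p was 1.2e-33, and the adjusted p was 0.290 with an estimated correlation. The fry adjusted p was 0.0246.

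In all, 83 of 15535 genes were called in ES cells with OHT, 81 higher and 2 lower. Of them, 22 were in the two-cell list and 36 had model names or were pseudogenes. The 10 largest named increases included Tdpoz4, at 5.45, and Tdpoz3, at 4.47, both of the two-cell list, and Tcstv3, at 5.19. They also included Usp17lb, at 4.51, and Usp17lc, at 4.38. Outside that list, AA792892 rose by 4.44 and Tie1, an endothelial receptor tyrosine kinase, by 4.39 on the log2 scale. H2-M10.4, a non-classical MHC class I gene, and Add2, encoding an adducin of the membrane skeleton, had 1 count in each untreated library and rose to 1.22 ± 0.172 and 1.02 ± 0.164 CPM (SD, n = 2). Lefty2, an inhibitor of Nodal signalling, fell from 205 ± 14.2 to 54.2 ± 14.2 CPM (SD, n = 2), a log2 fold change of -1.92 (SE 0.21, edgeR adjusted p = 0.0376). Its neighbour Lefty1 did not pass, with -1.36 and adjusted p = 0.0551, nor did B4galnt4 (-1.09), Exoc4 (-0.93), Ttc28 (-1.06) and Slc16a3 (-1.29). The split of 81 to 2 depends on the test: an unadjusted p under 0.05 was found for 2841 genes, 1631 higher and 1210 lower, and DESeq2 called 285 higher and 86 lower. The count of calls was 18 without untreated replicate 1, 20 without untreated replicate 2, 6165 (3053 higher, 3112 lower) without OHT replicate 1 and 4382 (2266 higher, 2116 lower) without OHT replicate 2, where the spread rests on the close untreated pair. Lefty2, AA792892, Tie1, Tcstv3, Tdpoz3, Tdpoz4, H2-M10.4 and Add2 were not called when either untreated library was left out, nor Usp17lc without untreated replicate 1.

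Lineage and germ cell lists also stood higher in ES cells with OHT. In the germline list, Stra8, a gene of meiotic entry, rose by 2.12 on the log2 scale, 1 of 23 members called (median 0.91, camera adjusted p = 9.4e-08, adjusted p = 0.364 with an estimated correlation). In the trophoblast list, Krt18, a simple-epithelium keratin, rose from 16.9 ± 2.15 to 42.8 ± 1.17 CPM, 1 of 14 members called (median 1.06, adjusted p = 0.000419, and adjusted p = 0.290 with an estimated correlation). No member was called in the smooth muscle (median 0.80), immediate early (0.57), senescence secretory (0.55), endoderm (0.53), fibroblast (0.53), epithelial (0.48) and striated muscle (0.47) lists. Their camera adjusted p ran from 0.000735 to 0.0116, and from 0.290 to 0.477 with an estimated correlation. With members at 0 in one group set at their bound, the senescence median was 0.15. Without OHT replicate 2 the senescence and smooth muscle calls were lost (medians 0.08 and 0.64, adjusted p = 0.223 and 0.244), and the trophoblast, immediate early, fibroblast and endoderm medians were 0.67, 0.33, 0.28 and 0.23. Without OHT replicate 1 the smooth muscle, senescence and endoderm medians were 1.26, 0.92 and 0.84. Stra8, Krt18 and Gbp2 were not called when either untreated library was left out. Among members that did not pass, Acta2 was at 1.40 and Ccn2 at 1.04 on the log2 scale. Gbp2, an interferon-induced GTPase, rose by 3.24 (edgeR adjusted p = 0.0106), 1 of 30 members called in an interferon list whose median was 0.08 (camera adjusted p = 0.0745). The interferon median was 0.028 with members at 0 in one group set at their bound, and 0.20 without untreated replicate 2.

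Lists of metabolism, repair and pluripotency stood lower in ES cells with OHT, with no single member called in any of them. The cholesterol synthesis list had a median of -0.39 with 19 of 21 members negative, among them Mvk at -0.74 and Nsdhl at -0.73 (camera adjusted p = 0.000419, adjusted p = 0.290 with an estimated correlation). The naive pluripotency list had a median of -0.27, with Tfcp2l1 at -0.87, Klf4 at -0.85 and Esrrb at -0.75 (adjusted p = 0.00475, and adjusted p = 0.391 with an estimated correlation). The homologous recombination and checkpoint list (-0.27), end joining (-0.24), telomere maintenance (-0.27), hypoxia and glycolysis (-0.29) and mitosis (-0.12) lists had camera adjusted p from 0.000735 to 0.0351, and from 0.290 to 0.682 with an estimated correlation. The naive pluripotency call was lost without OHT replicate 2 (median -0.19, adjusted p = 0.0669), the end joining call without OHT replicate 1 (median -0.09), and the telomere maintenance call without untreated replicate 1 or either OHT library (median -0.18 without OHT replicate 2). The mitosis call was lost without untreated replicate 1 and without OHT replicate 2, where the median turned to 0.04, and the median was -0.25 without OHT replicate 1. No list call was made for replication (-0.12), primed epiblast (-0.11, with Lefty2 its only member called), neural ectoderm (0.22), endothelium and blood (0.58), integrated stress response (0.01), oestrogen receptor targets (-0.12), cytosolic ribosome (0.02) and replication-dependent histones (0.14). Each of these medians moved by over 1.5 times with 1 or more of the left-out libraries. Replication was called lower without untreated replicate 2 (-0.20, adjusted p = 0.0143) or OHT replicate 1 (-0.29, adjusted p = 0.0109), and histones higher without untreated replicate 1 (0.48, adjusted p = 0.00342) but at -0.09 without untreated replicate 2.

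Transcripts of Trp53, which encodes the DNA damage response factor p53, and of its targets set the OHT-treated ES cell libraries apart. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) stood at 299 and 345 CPM in untreated ES cells, at 8.39 and 83.1 CPM with OHT, and at 8.98 and 7.82 CPM in FLICs without and with OHT. Its change in ES cells was not called (log2 fold change -2.82, SE 0.94, edgeR adjusted p = 0.214). It was -1.95 without OHT replicate 1 and -5.22 without OHT replicate 2. With the replicate number as a block, on 1 residual degree of freedom, it was called lower (-3.54, edgeR adjusted p = 0.000544). The call thus depends on how the spread is estimated. The p53 target Ccng1 stood at 276 and 302 CPM untreated, and at 45.2 and 295 CPM with OHT. Mdm2, the p53 ubiquitin ligase, stood at 182 and 202 CPM untreated, and at 79.8 and 356 CPM with OHT. None of the 39 p53 targets was called, and the list had a median of -0.22 (camera adjusted p = 0.00354, adjusted p = 0.693 with an estimated correlation). Without OHT replicate 1 that median was 0.09 (adjusted p = 0.270), and without OHT replicate 2 it was -0.97, so its direction rests on replicate 1.

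**Figure D2:**
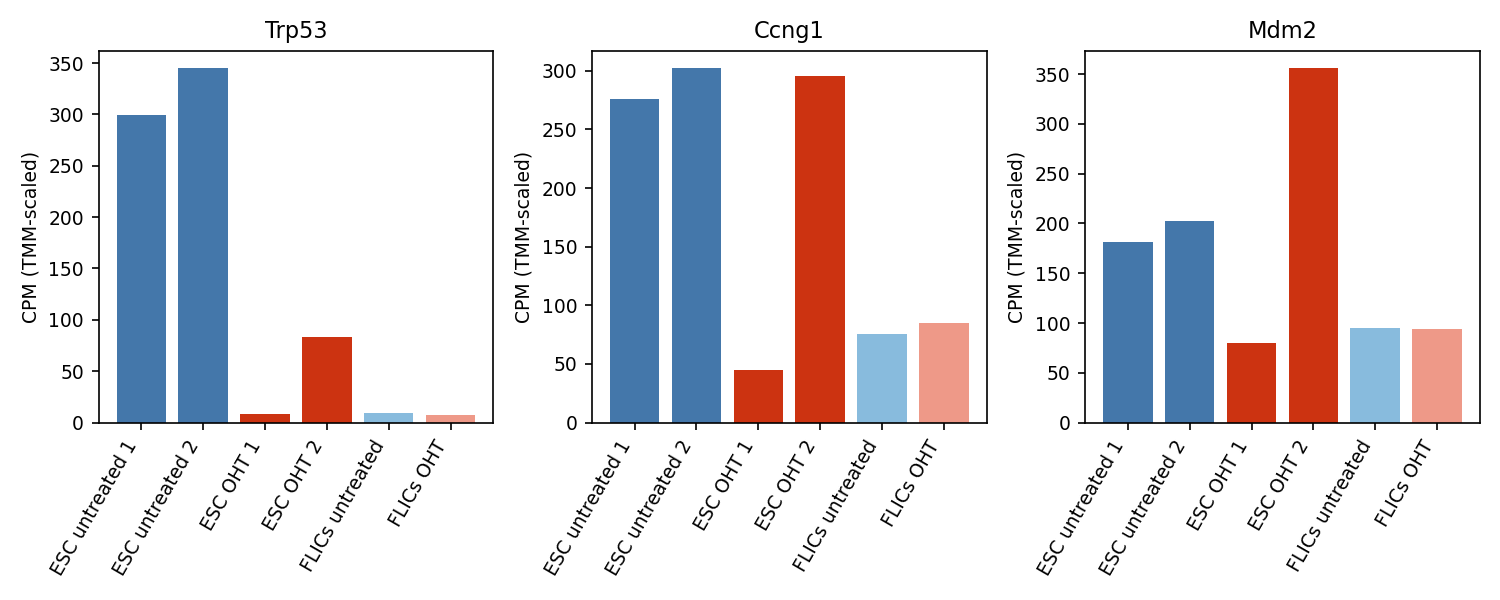
Bars give CPM (TMM-scaled) of Trp53, Ccng1 and Mdm2 in each of the 6 libraries, on linear axes from 0. ES cell OHT replicate 1 had 8.39 CPM of Trp53 and 45.2 CPM of Ccng1, against 83.1 and 295 CPM in OHT replicate 2.

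OHT in FLICs was compared in 1 library per condition, so the differences have no replicate check. Postn, a matrix protein of mesenchymal cells, stood at 13.0 CPM without and 47.3 CPM with OHT, a difference of 1.78 in log2(CPM + 1). Tcn2, the vitamin B12 carrier, stood at 20.2 and 57.7 CPM, Selenop at 15.9 and 39.2 CPM, and Bmp4 at 17.1 and 41.6 CPM. Tmem178, Pgm5, Serpinb1a, Cbr2, Islr and Cxcl15 were higher by 1.23 to 1.76 on that scale. Apart from Terf2, at -3.06, lower genes included Serpinb2 (-1.26), Dock8 (-1.22), Nup210 (-1.20), Zscan10 (-1.16) and Areg (-1.11). Also lower were Etv4 at 40.7 and 16.9 CPM, Dnmt3b at 54.5 and 24.2 CPM and Utf1 at 30.2 and 13.6 CPM. The Zscan4 family had a count of 0 in both libraries, which allows at most 0.0926 and 0.0686 CPM. By the size rule 62 of 11789 genes differed, 50 higher and 12 lower. Simulated FLICs libraries without any change, at the spread pooled over both ES cell pairs, gave 99 to 119 such genes. Biological coefficients of variation were 7.66% in the untreated and 26.0% in the OHT-treated ES cell pair. In the FLICs pair, which joins 1 untreated and 1 OHT library, it was 13.0% and includes any effect of OHT. By the same rule 0 of 12149 genes differed within the untreated ES cell pair and 470 of 12698 within the OHT-treated pair. Whether 62 stands above the spread of FLICs libraries therefore cannot be told.

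As groups, the fibroblast (median difference 0.45), smooth muscle (0.42) and cholesterol synthesis (0.26, higher in 21 of 21 members) lists stood above each of the 10000 random lists in FLICs with OHT. Immediate early (0.21), interferon (0.20), stress response (0.17) and p53 target (0.11) lists also lay above the central 95% of random lists. The primed epiblast list (-0.34) lay below each random list, and the homologous recombination list (-0.08) below the central 95%. Random lists do not measure the spread between libraries of one condition. Between the OHT-treated ES cell libraries, for example, the p53 target median differed by -0.997, against -0.14 to 0.16 in random lists. With 1 library per condition, these positions therefore cannot tie a list to OHT. The two-cell list had a median of 0, but only 10 of its 50 members had a mean of at least 1 CPM in FLICs. For most members a fall could thus not be measured there, whereas a rise could. The Zscan4 sum had a count of 0 in FLICs with OHT, against 303 CPM in ES cells with OHT. No rise of that size was thus seen in this 1 pair of FLICs libraries. Across 10866 genes expressed in both cell types, the OHT differences in ES cells and in FLICs had a Pearson r of 0.158 and a Spearman rho of 0.123, over genes that are not independent replicates.

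**Figure D3:**
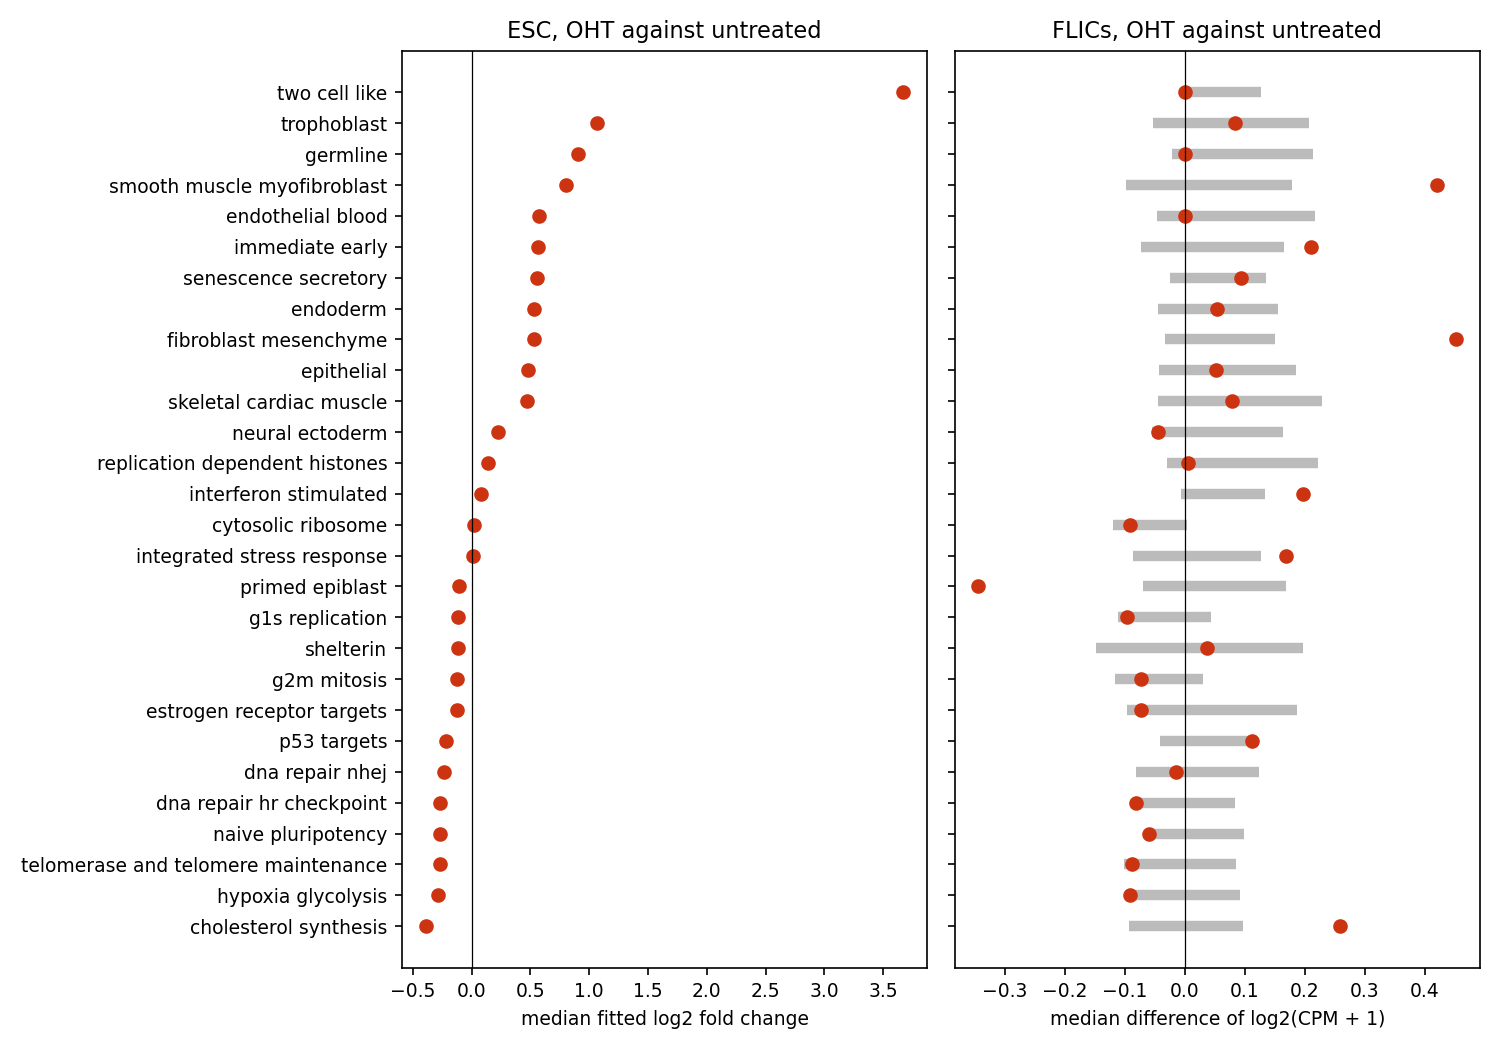
Points give the median OHT difference of each of 28 gene lists in ES cells (left, fitted log2 fold change) and in FLICs (right, difference of log2(CPM + 1)), and grey bars give the central 95% of 10000 matched random lists. The two-cell list stands at 3.67 in ES cells and at 0 in FLICs, where only 10 of its 50 members had a mean of at least 1 CPM. The 2 scales differ.

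Without OHT, FLICs differed from ES cells in 8532 of 15535 genes, 4074 higher and 4458 lower. Mesenchymal genes were higher: 27 of 30 fibroblast list members were called higher and 2 lower (median 5.28, camera adjusted p = 2.5e-09, adjusted p = 0.421 with an estimated correlation), and 10 of 12 smooth muscle members were called higher (median 4.16, adjusted p = 0.00246, and adjusted p = 0.561 with an estimated correlation). Acta2, smooth muscle actin, stood at 0.777 ± 0.0685 CPM (SD, n = 2) in ES cells and 5936 CPM in FLICs. Vcam1, an adhesion molecule, had no count in untreated ES cells and 164 CPM in FLICs, at least 3708-fold higher against 3 counts over the group. On the same basis Cav1, Ptx3, Megf10 and Ifi204 were at least 3277-fold, 3175-fold, 2073-fold and 1798-fold higher. Pcdh7, Col8a1, Ccl2 and Ccn4 had no count in untreated ES cells either and stood at 67.3 to 78.1 CPM in FLICs, and Col12a1 stood at 384 CPM. Senescence secretory genes (16 of 20 higher, median 4.83), immediate early genes (12 of 16 higher, median 2.99) and cholesterol synthesis genes (15 of 21 higher, median 0.96) were the other lists called higher, with adjusted p from 0.421 to 0.532 with an estimated correlation.

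Pluripotency genes were lower in untreated FLICs than in untreated ES cells. Each of the 31 naive pluripotency members was called lower (median -5.43, camera adjusted p = 2.3e-14, adjusted p = 0.421 with an estimated correlation). Zfp42, also known as Rex1, stood at 104 ± 7.0 CPM (SD, n = 2) in untreated ES cells and had no count in untreated FLICs, at least 1125-fold lower against 3 counts. Tfcp2l1, Nr5a2 and Laptm5 were at least 1431-fold, 950-fold and 1133-fold lower, and Pla2g1b and Dnah8 at least 1807-fold and 1046-fold lower. Nlrp4f, Inpp5d and Rbmxl2 also had no count in untreated FLICs, and Dppa5a had 1 count there against 589 ± 78.0 CPM in untreated ES cells. Germline genes (22 of 23 lower), two-cell genes (29 of 50), epithelial genes (10 of 16), recombination and checkpoint genes (17 of 31) and p53 targets (18 of 39, with 3 higher) were the other lists called lower, with adjusted p from 0.478 to 0.778 with an estimated correlation. The germline and two-cell medians were -8.22 and -4.42 as fitted, and -5.48 and -1.75 with members at 0 set at their bound. With OHT, 8967 genes differed between the cell types, 4410 higher and 4557 lower in FLICs. The count without OHT was 5375 without untreated ES cell replicate 1 and 5391 without untreated replicate 2.

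**Figure D4:**
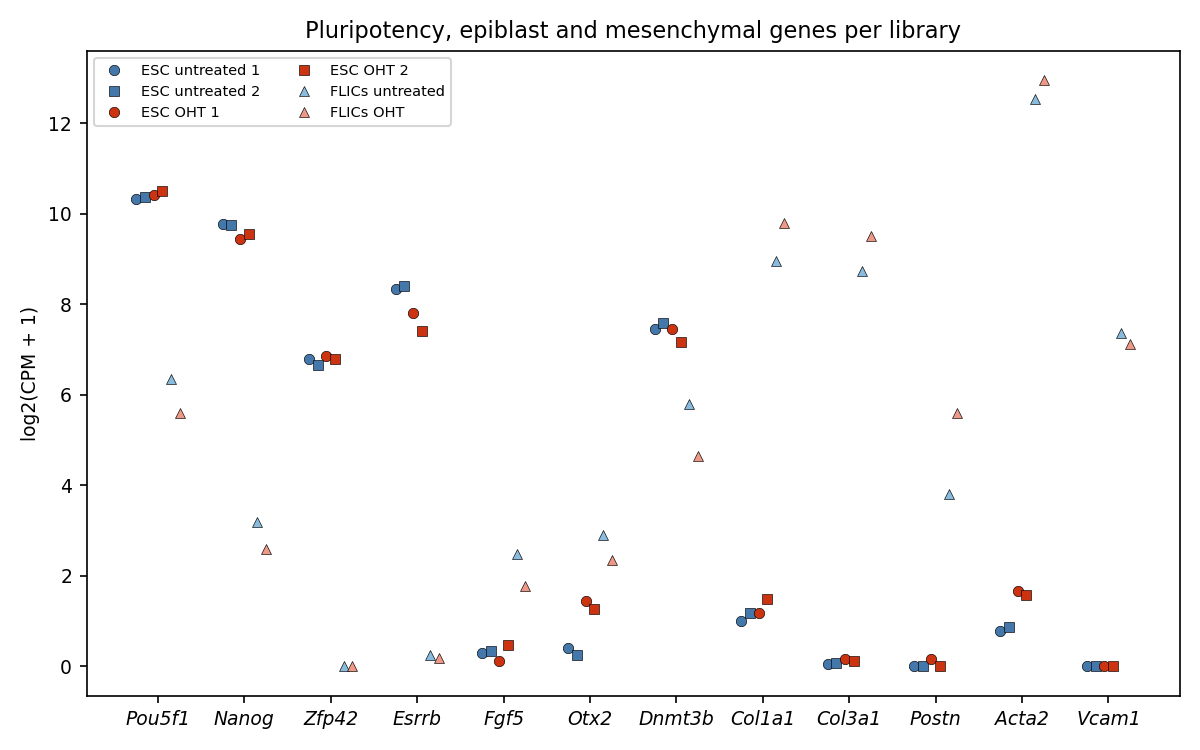
Points give log2(CPM + 1) of pluripotency, epiblast and mesenchymal genes in each of the 6 libraries. Zfp42 stands at 0 in both FLICs libraries, and Acta2 is higher in FLICs (5936 CPM untreated) than in untreated ES cells (0.777 CPM).

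Whether the response to OHT differed between the cell types was tested by the interaction term, with each FLICs library assumed to vary like the ES cell libraries. No gene was called by edgeR's quasi-likelihood test (smallest adjusted p = 0.638), 1057 had an unadjusted p under 0.05, and DESeq2 called 20. That test could not call a gene with no count in both FLICs libraries, since the SE of its term has no bound. Zscan4d, for which the SE was 4268, is such a gene, as are others with large increases in ES cells. The lack of calls therefore does not show that the responses were alike. Genes with the smallest p-values and named here included Gbp2, at 0.331 and 0.373 CPM in untreated and 3.46 and 3.25 CPM in OHT-treated ES cells, and at 14.0 and 27.2 CPM in FLICs without and with OHT. Its interaction term was -2.28 (edgeR adjusted p = 0.638). Ankrd1 (-2.65), Osgin1 (-2.95), Pim2 (-1.72) and Fgf7 were the others with a lower response in FLICs, and Dusp27 (2.09), Spats2l (2.05), Islr2 (3.39), Tnfrsf1b (2.15) and Map10 those with a higher one, none of them called. The interaction count was 2804 without ES cell OHT replicate 1 and 2047 without OHT replicate 2.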

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

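The list tests of the interaction, and the tests of the low p53 targets other than that of the chromosome 11 stretch, were chosen only after the results were seen. For 4 lists the OHT response differed between FLICs and ES cells by camera on the interaction term. The two-cell list had a median interaction of -3.36 on the log2 scale (adjusted p = 2.2e-37), the germline list -0.45 (adjusted p = 5.0e-05), the cholesterol synthesis list 0.68 (adjusted p = 2.9e-06) and the p53 target list 0.47 (adjusted p = 0.0235). With an estimated correlation none of them passed, with adjusted p of 0.470, 0.664, 0.470 and 0.760 in that order. None passed with fry either, with fry adjusted p of 0.0633, 0.306, 0.0633 and 0.709. Many two-cell and germline genes had no count in FLICs, where a fall could then not be measured, though a rise could. The p53 target difference was 0.05 without ES cell OHT replicate 1, where it no longer passed, and 1.33 without OHT replicate 2, and the germline difference was -0.24 without OHT replicate 2.

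The low p53 targets of ES cell OHT replicate 1 go with low Trp53 there, at 2.61% of the untreated mean. Scaling or depth is argued against by the median difference of -0.997 from replicate 2, against -0.14 to 0.16 in random lists, and a swap with an untreated library by Terf2 at 1.49% of the untreated mean. Admixed FLICs are argued against by the 100 most FLICs-specific genes, whose median stood at 0.431% of the FLICs level, and loss of the surrounding chromosome 11 stretch by the 18 genes within 200 kb, whose median change was -0.0786. Whether low Trp53 lowered the targets stays open. FLICs without and with OHT had Trp53 at 2.79% and 2.43% of untreated ES cells. They also had low target medians (-1.13 and -1.02, below their random ranges) but are another cell type. OHT replicate 2, with Trp53 at 25.8% of untreated ES cells, had a target median of 0.0836. That is slightly above its random range of -0.211 to 0.0817. The labels name no change of Trp53, and whether its loss was selected, engineered or chance was not tested.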

How the results depend on the processing

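Alternatives were planned before the data were examined, except those on the interaction of lists. The 83 genes called with OHT in ES cells became 371 with DESeq2 (285 higher and 86 lower), 262 without the count filter, 46 with at least 5 CPM in 2 libraries and 148 in the ES cell libraries alone. All 83 were shared with DESeq2, with no filter and with relative log expression scaling (114 genes), and 8 of 8 Zscan4 genes were called in each of these settings. Leaving out each ES cell library gave 18 to 6165 genes. Between FLICs and ES cells the counts ran from 5375 to 12025 without OHT and from 6849 to 11786 with OHT when a library was left out. The interaction count of 0 became 20 with DESeq2 and 0 to 2804 with a library left out. By construction, a fit without an ES cell library takes its spread from the remaining pair alone, and the high counts are those that rest on the close untreated pair. The cause of the other changes was not tested.

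The labels do not say what the replicate numbers of the ES cell libraries share, and the correlation of deviations over the 2 pairs was 0.345. As a hint from the data, not the design, Y-linked Ddx3y had 19 and 82 counts in the replicate 1 libraries and 0 in both replicate 2 libraries, so the number follows a property of the cells. With the replicate number as a block, the fit had 1 residual degree of freedom. It called 1206 genes with OHT in ES cells (814 higher and 392 lower, all 83 shared) and 17 in the interaction. Trp53 was called lower with OHT (-3.54, edgeR adjusted p = 0.000544). Its level, however, was 2.61% of the untreated mean in OHT replicate 1 and 25.8% in OHT replicate 2. The p53 target median was -0.50 instead of -0.22.

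In FLICs the 62 genes became 1 at 4-fold, 37 at 5 CPM, 189 with a pseudocount of 0.1, 8 with a pseudocount of 5 and 0 in the pooled-spread fit, where 639 genes had an unadjusted p under 0.05 and DESeq2 called 4. Of the 28 lists, 18 were called with OHT in ES cells, 0 with an estimated correlation and 5 with fry. The 5 were the two-cell, immediate early, fibroblast, striated muscle and cholesterol synthesis lists (fry adjusted p from 0.0246 to 0.0492). With an estimated correlation no list was called in any comparison, even naive pluripotency in FLICs, where 31 of 31 members were called lower. On 2 residual degrees of freedom that test cannot tell these lists apart. Between FLICs and ES cells without OHT, 11 of the 28 were called, 0 with an estimated correlation and 17 with fry, of which 10 were shared. Of 4 interaction lists, 0 were called with an estimated correlation and 0 with fry. The p53 target list turned from -0.22 to 0.0889 without OHT replicate 1 in ES cells and ran from -0.968 to 0.0889 over the left-out libraries. The cause of the remaining changes was not tested. Depth limits genes near the floor of 0.0686 to 0.118 CPM.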

Other observations

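The tests on pluripotency transcripts in FLICs were chosen only after the results were seen. Those on chromosomes were set before their own results were seen, but on chromosomes 6, 8 and 16, which have the largest shifts between the OHT libraries. FLICs kept some transcripts of pluripotent cells and lacked others. Lin28a stood at 12.1%, Utf1 at 8.46% and Pou5f1, which encodes Oct4, at 6.21% of the untreated ES cell level, whereas 13 of the 31 naive genes were under 1%. Otx2, a gene of the primed epiblast, stood at 6.48 CPM in untreated FLICs against 0.259 ± 0.102 CPM (SD, n = 2) in untreated ES cells. Esr1, the oestrogen receptor gene, stood between 109 and 172 CPM in the 6 libraries.

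Residual undifferentiated ES cells would bring all their abundant transcripts at about 1 share. Of the 28 naive genes with at least 50 CPM in ES cells, 9 stood under 0.1 of the Pou5f1 share, which argues against that source. The 33 naive and primed genes with at least 1 CPM in untreated FLICs were lower with OHT in 26 cases. Their median difference was -0.43, below the random range of -0.04 to 0.21. Since the genes were kept by their untreated level, and the random lists were not, part of that difference may come from the filter. A share of epiblast-like cells that was smaller in the OHT library is a candidate explanation, from 1 library per condition, and a fall within all cells stays open.

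Replicate 1 and replicate 2 of the ES cells differed in the medians of some chromosomes, with 6 of 20 outside the range of random gene sets in the same direction in both pairs. Between the OHT libraries, replicate 1 minus replicate 2, the median log2 difference was 0.34, 0.29, -0.33, -0.21, -0.13 and 0.13 on chromosomes 6, 8, 16, X, 11 and 19, and between the untreated libraries 0.16, 0.18, -0.14, -0.11, -0.07 and 0.05. For chromosomes 6, 8 and 16 a bias of GC content or gene length is argued against, since the smallest of these 3 medians between the OHT libraries was still 0.29 in size after removal of that trend, but not for chromosome 19 in the untreated pair, which fell to 0.02, inside its random range. Chromosomes 6, 8 and 16 were each split by gene order into 4 equal parts. Between the OHT libraries, 12 of 12 parts lay outside the range of random gene sets in the direction of their chromosome. Whole-chromosome copy number differences between the cultures may give such a pattern. As these chromosomes have the largest shifts, that outcome depends in part on their choice. No copy number was measured, and no biological explanation named by the design was tested.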
